A study of Mus musculus with 59 samples.

How the data were processed

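The series holds RNA sequencing of mouse liver, kidney, plasma and VsWAT (named here as in the labels) from input, pull-down and total RNA libraries on a high-fat or low-fat diet. Per the labels, tissues were frozen after dissection and their RNA was extracted with NucleoZOL, plasma was passed through a spin filter and its RNA extracted with Tri reagent BD, and libraries were made with the CATS small RNA kit of Diagenode. The labels give 1 kit for all libraries, including those named mRNA, and do not say how mRNA and small RNA were separated. The deposited files hold raw counts per feature, 1 file per library, made by the authors with STAR and HTSeq on mm10, per the submitters' processing notes. Versions, the annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. Without a stated strand, reads of overlapping genes cannot be told apart, and a microRNA gene's count holds any read over its locus, mature or precursor. The human transgene is not part of mm10 and was not counted.

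Each file listed 55273 features, of which 54838 were Ensembl mouse genes and 435 tRNA genes, with 0 summary rows of unassigned reads. Symbols were matched by Ensembl identifier for 54723, and coordinates and gene classes come from the RefSeq table of GRCm38.p6, the assembly of mm10, which gave a biotype for 38044 symbols. All 59 libraries were placed in 22 groups by tissue, RNA kind, fraction, diet and the number in their titles. The files hold reads and no molecular identifiers, so floors cover counting error only. A count of 0 was bounded by a floor of 3 counts over the group.

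Gene tests used edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on the deposited counts, separately in each of the 6 sets, with TMM scaling, filterByExpr by group (minimum count 10, minimum total 15), 1 coefficient per group and the quasi-likelihood F test. Adjusted p is the Benjamini-Hochberg value of this test over the tested genes of a contrast, with calls at 0.05. The standard error of a log2 change is its size divided by the square root of F. Contrasts were pull-down minus input averaged over diets, high-fat minus low-fat within each fraction, and the difference between these diet changes. A model of both liver and kidney mRNA tested whether their pull-down changes differ. A fold is that of the fitted log2 change. Group means with an SD are in CPM of the TMM-scaled tested genes, and other CPM values are counts per library total. The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Where leaving out or summing libraries leaves 1 in a group (plasma, kidney low-fat, liver small RNA pull-down low-fat, kidney input high-fat with 2 left out, and liver mRNA input low-fat with its close pair summed and low-fat 1 left out), the lone library is assumed to vary like the other groups.

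Before the data were examined, the groups, contrasts, tests, 38 gene lists, a first set of other settings and the rule for named genes were fixed. The rule took, per contrast, genes with an adjusted p under 0.05, at least median expression and a proper symbol, without overlap between diets in diet contrasts, up to the 8 largest rises and 8 largest falls (4 of each among microRNAs and among other genes in small RNA), the 3 smallest p where fewer than 3 passed, up to 4 members of each list that passed, and genes fixed by name (Cyp3a11, Cyp3a13, Cyp3a25, Cyp7a1, Scd1, Sqle, Cyp4a14, Cidea and Cidec in liver mRNA, Lrp2, Slc34a1, Umod and Aqp2 in kidney, Alb, Mir122, Mir33 and Mir192 in small RNA, and Lep, Adipoq, Scd1 and Fasn in VsWAT total RNA). The text prints a part of them. A few of the genes it took are not reported here. Mir6236, Xist, the Y-linked genes, sex-biased liver genes, the further Cyp3a genes and the mitochondrial mRNAs with few counts were singled out after their values were seen. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Camera compares a list with all other genes; fry asks whether a list's genes move, on balance, in one direction. RNA classes were summed as percent of counts and compared with a two-sided exact permutation test of the difference of means, adjusted over 30 class shares and 25 parts of classes. Overlaps of calls were compared with Fisher's exact test against independent lists. The sets and fractions compared in this way share no libraries. The diet changes of input and pull-down were correlated across genes, as a description with no p.

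Whether shared replicate numbers pair libraries was checked by correlating deviations from group means over genes. Across diets, same-numbered liver mRNA pull-down libraries correlated over 0.1 in all 3 pairs (0.23 to 0.29), which meets the threshold set for pairing, and a block by number gave 502 called genes for diet there against 647 without it. The block changed the call of none of the 27 lists tested there. Kidney offered 2 same-numbered pairs per fraction, too few for that check. They correlated at 0.131 to 0.5557, but with 2 low-fat libraries the deviations mirror each other, and a block by number called 0 genes for diet in input and in pull-down, as without it, and changed the call of 0 of 32 lists in input and 2 of 32 in pull-down, neither of them given in the report. The other sets did not meet the threshold, so their block fits are given only among the other settings. For input and pull-down of equal number it was applied over both diets together. There VsWAT small RNA had 5 of 6 pairs over 0.1 (0.01995 to 0.4024), so its pull-down results come from an unpaired fit although pairing is possible. The liver mRNA input libraries high-fat 1 and 3 and low-fat 2 and 3 were closer to each other than other pairs. Their chi-square per degree of freedom was 1.18 and 1.13 over genes with at least 20 counts, against 3.235 to 62.49 in the other liver mRNA pairs. They differed beyond sampling noise (chi-square p = 7.352e-35 and 3.662e-19), so each was kept as a library and summing them was an alternative. This test does not show separate samples, since repeat libraries of 1 sample could differ so too. VsWAT small RNA input high-fat 1 and 2 were close too (1.527, against 9.43 and 8.832 for the other pairs of that group). VsWAT total RNA high-fat 1 and 2 were at 3.358, against 23.39 and 25.86. These VsWAT pairs were not summed, so how the results would change if their libraries are repeats was not tested.

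Settings chosen at that stage were DESeq2 1.42.0, RLE factors, no low-count filter, a filter at 10 CPM, a replicate block, only the groups compared, each library left out in turn, the most counted gene left out of class shares, a log2 change over 1 in overlaps and the upper part of genes by expression in correlations. Chosen after seeing the data were scaling to total counts, summing the close liver input pairs with and without input low-fat 1, leaving out the plasma pull-down libraries high-fat 2 and low-fat 2, leaving out kidney input high-fat 2 and 3 together, a crossed pairing in plasma input, a block by number among liver mRNA pull-down libraries only, a block in kidney list tests, and the Mir122 pull-down change within each diet. The gene test was tested on simulated data drawn from the means, spread and library sizes of each set, with 200 genes changed by known folds. These were chosen among genes with a mean count of at least 20, and each gene took the spread of the trend over expression. Recovery of genes with fewer counts or a wider spread is therefore not covered. At a 2-fold change it recovered 96% in liver mRNA pull-down against input (10580 genes), 66% in kidney, 78% in liver small RNA and 58% in VsWAT small RNA, and for diet 68% in liver mRNA input, 74% in liver mRNA pull-down and 58% in VsWAT total RNA. For the difference of diet changes in liver mRNA it recovered 20%. Figures and checks used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.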

Results

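RNA from the liver, kidney, plasma and a tissue labelled VsWAT of mice was sequenced after high-fat or low-fat feeding. The series design text describes male mice of 12 weeks on either diet for 2 weeks. The mice carried a knockout of Cyp3a13, a deletion from Cyp3a57 to Cyp3a59 and a human CYP3A4 transgene driven by APOE sequences, CYP3A4 being a drug-metabolizing cytochrome P450. The series title names a labelling of RNA, iTag, and the libraries are labelled input or pull-down. Here a pull-down library is read as the RNA recovered by the tag and an input library as the RNA before recovery, and the labels do not say which cells were tagged. The 59 libraries fall into 22 groups in 6 sets. Liver mRNA had 6 input and 6 pull-down libraries, with 3 per diet. Kidney mRNA had 5 of each, with 3 high-fat and 2 low-fat. Liver small RNA had 6 input and 5 pull-down libraries, since pull-down low-fat 2 was not analysed here. VsWAT small RNA had 6 of each, plasma small RNA 4 of each, with 2 per diet, and VsWAT total RNA, made without a pull-down, had 6 libraries.

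Liver mRNA libraries held 3033702 to 4942158 counts in input and 3389320 to 4426392 in pull-down, and kidney mRNA libraries 7970076 to 19645443 and 3741335 to 13713002. Liver small RNA libraries held 875970 to 3608065 counts in input and 573697 to 3338652 in pull-down. VsWAT small RNA libraries held 881578 to 2220123 and 1867345 to 2580104 counts, and VsWAT total RNA libraries 2556411 to 7940309. Plasma was the shallowest set, with 327144 to 828030 counts in input and 221875 to 646964 in pull-down, where 7871 to 12922 features were detected in input libraries and 2863 to 6059 in pull-down libraries.

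The targeted genes were read first. Cyp3a13 (chromosome 5) was still counted in every liver mRNA library, at 5.6 to 156 CPM (counts scaled to the library total), and Cyp3a57 and Cyp3a59 reached at most 11.7 and 37.7 CPM. Cyp3a41a, Cyp3a41b and Cyp3a44 had 0 counts in all 12 liver mRNA libraries, which allows up to 0.0662 CPM over the set. Cyp3a25 was at 0 to 3.54 CPM, Cyp3a16 at 1.65 to 173 CPM and Cyp3a11 at 0 to 37.6 CPM. In the GRCm38.p6 annotation these 6 genes lie between Cyp3a57 and Cyp3a59. Cyp3a genes are close copies of each other, so reads could be split between them, and a count over a whole gene does not show which part of it was read, so these counts do not check the labels. In input, Cyp3a13 averaged 131 ± 41.1 TMM-scaled CPM (SD, n = 3) on high fat and 59.7 ± 45.7 (SD, n = 3) on low fat. The lowest Cyp3a13 value, 17 counts (5.6 CPM), was that of input low-fat 1. The same library held the lowest values of Cyp3a16 (1.65 CPM), Cyp3a57 and Cyp3a59 (0.33 CPM each). It lowers the low-fat means, so a feature of this single library cannot be told from diet here. Cyp3a11 was 3.89-fold higher on high fat in input (log2 change 1.96 ± 0.50 SE, edgeR adjusted p = 0.01381), a call that ended when only the groups compared entered the fit (adjusted p = 0.114). In pull-down against input Cyp3a11 was 1.84-fold higher (adjusted p = 0.02848), a call that 7 of the 12 fits without 1 library ended.

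To ask which transcripts the tag recovered in liver, pull-down was compared with input over both diets. Ribosomal protein genes and nuclear-encoded genes of the respiratory chain were lower in pull-down, and clock genes were higher. Of 34 cytosolic ribosomal protein genes 33 fell, with a median log2 change of −1.69 (camera adjusted p = 2.293e-06; adjusted p = 0.377 with an estimated correlation), Rplp0 by 3.52-fold. All 26 tested nuclear-encoded respiratory chain genes fell, with a median of −1.48 (camera adjusted p = 6.963e-09; adjusted p = 0.182 with an estimated correlation), among them Sdha, a subunit of succinate dehydrogenase, by 2.91-fold (log2 change −1.54 ± 0.07 SE, edgeR adjusted p = 1.488e-08). The mitochondrially encoded mRNAs went the other way gene by gene: 6 of 7 rose and none fell, 6 adjusted over the list alone, although the list did not pass (median 0.63, camera adjusted p = 0.1268; adjusted p = 0.3916 with an estimated correlation), and their share of counts rose from 7.94 to 14.3% (two-sided exact permutation p = 0.002165, adjusted p = 0.007732 over 25 parts of classes). Of 19 circadian clock genes 17 rose and none fell, 18 adjusted over the list alone, with a median of 1.22 (camera adjusted p = 5.769e-06; adjusted p = 0.182 with an estimated correlation). Bhlhe40, a clock repressor, rose 3.41-fold (log2 change 1.77 ± 0.13 SE, adjusted p = 1.201e-07), Ciart 2.90-fold and Rora 2.81-fold. Of 19 immediate early genes 14 rose and 4 fell (camera adjusted p = 0.009728; adjusted p = 0.182 with an estimated correlation), with Myc 4.10-fold and Egr1 2.53-fold higher. Of 21 genes of glucose production and insulin signalling 13 rose and 5 fell (camera adjusted p = 0.03611; adjusted p = 0.182 with an estimated correlation), among them Tat, of tyrosine breakdown, by 4.95-fold (log2 change 2.31 ± 0.12 SE, adjusted p = 1.591e-08) and Foxo1, a transcription factor that insulin restrains, by 2.83-fold. Cited2, Cpeb2 and Ocln rose 4.63-, 5.29- and 4.86-fold, and Mir122, counted here as the gene of a liver microRNA, 8.97-fold over both diets. That average joins 2.40-fold on high fat (adjusted p = 0.00346) and 33.5-fold on low fat (adjusted p = 2.158e-06), where input libraries held 3 to 9 counts.

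Markers of liver cells other than hepatocytes fell together, and so did most hepatocyte markers. Of 17 endothelial markers 16 fell (median −2.12, camera adjusted p = 7.247e-09, and 0.0249 with an estimated correlation), Stab2 by 5.52-fold. All 13 stellate cell and fibroblast markers fell (median −2.20, camera adjusted p = 1.123e-07, and 0.0257 with an estimated correlation), among them the matrix proteoglycan Dcn by 10.6-fold (log2 change −3.41 ± 0.23 SE, edgeR adjusted p = 7.456e-08) and Lrat, which stores retinol, by 4.14-fold. All 14 macrophage and Kupffer cell markers fell (median −1.76, camera adjusted p = 5.359e-06; adjusted p = 0.123 with an estimated correlation), with Csf1r 6.97-fold and Vsig4 5.65-fold lower. Of 24 hepatocyte markers 20 fell and 3 rose (median −1.65, camera adjusted p = 1.123e-07; adjusted p = 0.123 with an estimated correlation). Vtn, Serpina1a and F2, which encode secreted plasma proteins, fell 4.75-, 3.85- and 3.18-fold. Of 16 extracellular matrix genes 14 fell (median −1.32, camera adjusted p = 2.18e-04; adjusted p = 0.172 with an estimated correlation). Among 25 genes of drug and xenobiotic metabolism 19 fell and 4 rose (median −1.12, camera adjusted p = 1.38e-05, and 0.0257 with an estimated correlation), Cyp1a2 by 3.16-fold. Of 31 genes of fatty acid oxidation and PPAR-alpha targets 19 fell and 7 rose (median −0.85, camera adjusted p = 6.763e-04, and 0.0257 with an estimated correlation). Of 22 acute phase genes 13 fell and 2 rose (camera adjusted p = 0.005626; adjusted p = 0.377 with an estimated correlation). Except for the clock list, the counts adjusted over the list alone were the same.

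Across the liver, edgeR called 8022 of 10865 tested genes, 4097 higher and 3925 lower in pull-down. Scaling to total counts in place of TMM moved the median of all genes from 0.02 to 0.27 and gave 4799 higher and 3151 lower, so directions here are relative to the typical gene. Ribosomal protein, serpin and P450 genes have close copies that could share reads.

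**Figure D1:**
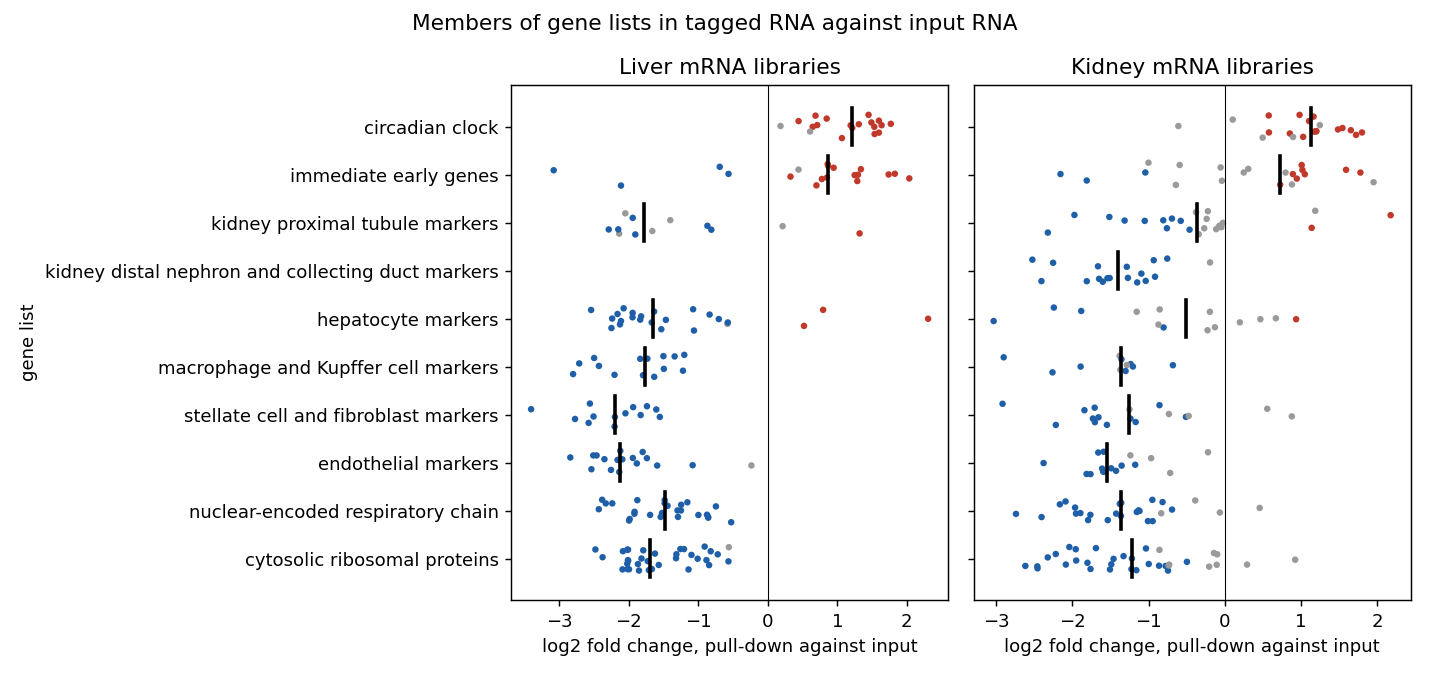
Log2 change in pull-down against input for each tested member of 10 fixed gene lists in liver mRNA and kidney mRNA, with a black bar at each list's median; red points were higher and blue points lower at an edgeR adjusted p under 0.05, and grey points did not pass. Ribosomal protein genes (medians −1.69 in liver and −1.22 in kidney) lie below 0 and circadian clock genes (medians 1.22 and 1.14) above 0.

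In kidney pull-down too, most ribosomal protein and respiratory chain genes were lower and most clock genes higher. Of 34 ribosomal protein genes 25 fell (median −1.22, camera adjusted p = 9.357e-12; adjusted p = 0.283 with an estimated correlation), Rpl37 by 6.14-fold, and of 26 respiratory chain genes 22 fell (median −1.36, camera adjusted p = 1.39e-13; adjusted p = 0.22 with an estimated correlation), Cox7a2 by 6.68-fold. Of 20 clock genes 15 rose and none fell, 16 adjusted over the list alone (camera adjusted p = 3.636e-06; adjusted p = 0.22 with an estimated correlation). Per1, a core clock gene, rose 3.48-fold (log2 change 1.80 ± 0.24 SE, edgeR adjusted p = 9.615e-05), Per2 3.15-fold, Bhlhe40 3.30-fold and Ciart 2.92-fold. Cyp27b1, which activates vitamin D, rose 5.64-fold (log2 change 2.50 ± 0.45 SE, adjusted p = 6.126e-04). Of 18 markers of the distal nephron and collecting duct 17 fell (median −1.40, camera adjusted p = 8.377e-10; adjusted p = 0.22 with an estimated correlation), with Umod, a secreted protein of the loop of Henle, 4.77-fold lower, Hsd11b2 3.51-fold lower and the water channel gene Aqp2 2.14-fold lower. Of 22 proximal tubule markers 10 fell and 2 rose, 3 adjusted over the list alone (median −0.36, camera adjusted p = 0.01894; adjusted p = 0.325 with an estimated correlation). Slc34a1, a phosphate transporter, fell 1.69-fold, and Lrp2, the megalin receptor, did not pass the test (log2 change −0.07 ± 0.17 SE, adjusted p = 0.7379), with a positive value under total-count scaling. Kap, an androgen-regulated gene of the proximal tubule, fell 5.00-fold.

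Markers of other kidney cell types were lower in kidney pull-down. Of 16 endothelial markers 12 fell (median −1.54, camera adjusted p = 3.921e-05; adjusted p = 0.283 with an estimated correlation), Emcn by 5.2-fold and Kdr by 3.05-fold. Of 12 podocyte and glomerular markers 8 fell (camera adjusted p = 0.001208; adjusted p = 0.283 with an estimated correlation), and of 10 erythroid and platelet genes 6 fell (camera adjusted p = 3.144e-04; adjusted p = 0.22 with an estimated correlation), the globin gene Hbb-bs by 10.1-fold. Of 17 stellate cell and fibroblast markers 12 fell, with 13 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.176e-04; adjusted p = 0.283 with an estimated correlation). Of 11 macrophage markers 8 fell, 11 adjusted over the list alone (camera adjusted p = 0.002362; adjusted p = 0.283 with an estimated correlation). In all, edgeR called 7961 of 15023 genes, 3999 higher and 3962 lower, and total-count scaling gave 5080 and 2899 with the median of all genes moved from 0.01 to 0.23. Of 10358 genes tested in both tissues 2598 rose in both, where independent lists would share 1222, 2316 fell in both against 1007, and 201 were called in opposite directions. The log2 changes of the tissues correlated across genes, which are not independent replicates, at r = 0.765.

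The difference between liver and kidney in the pull-down change was tested in one model of both tissues. Nr0b2, which encodes a repressor of bile acid synthesis, was recovered more in liver than in kidney (difference of log2 changes 4.37 ± 0.73 SE, edgeR adjusted p = 4.017e-04), as was the growth factor gene Egf (3.25 ± 0.31). Recovery was lower in liver for Lrat (−3.11 ± 0.35), Acaa1b, a peroxisomal thiolase (−3.17 ± 0.45), Slc13a3, a dicarboxylate transporter (−1.96 ± 0.33), Reln (−1.89 ± 0.26) and the water channel gene Aqp1 (−1.76 ± 0.27). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, passed narrowly (3.56 ± 1.12, adjusted p = 0.04046) and lost its call in 10 of 27 alternatives, where the value lay between 2.26 and 3.58. Of 18 stellate cell and fibroblast markers 3 were lower in liver (median −1.09, camera adjusted p = 0.003097; adjusted p = 0.476 with an estimated correlation), and of 22 proximal tubule markers 4 were lower (median −1.08, camera adjusted p = 0.009106; adjusted p = 0.678 with an estimated correlation). Of 15 mitochondrial tRNA and rRNA genes 3 were higher in liver (median 1.28, camera adjusted p = 9.462e-06; adjusted p = 0.476 with an estimated correlation). Of 13724 genes tested 515 were higher and 1227 lower in liver. This split turned with the scaling and the filter, to 750 and 816 with RLE factors, 849 and 648 with total counts and 1186 and 615 among genes of at least 10 CPM. The count was 2642 without liver input low-fat 1 and 1149 without kidney input low-fat 1.

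Diet changed the liver transcriptome in input libraries, with lipid synthesis lower and endoplasmic reticulum chaperones higher on high fat. Scd1, which makes monounsaturated fatty acids (chromosome 19, 44394450 to 44407709, GRCm38.p6), fell 62.9-fold, from 13582 ± 2356 TMM-scaled CPM on low fat to 216 ± 12.5 on high fat (SD, n = 3 each; log2 change −5.98 ± 0.20 SE, edgeR adjusted p = 4.3e-09). Of 25 genes of fatty acid and triglyceride synthesis 20 fell and none rose, 22 adjusted over the list alone (median −1.40, camera adjusted p = 1.492e-34, and 5.00e-04 with an estimated correlation). Fasn, the fatty acid synthase, fell 17.4-fold, Acacb 11.9-fold, Acaca 5.63-fold and Elovl6 3.98-fold. Of 23 genes of the unfolded protein response 15 rose and none fell, with 17 higher and 1 lower adjusted over the list alone (median 0.97, camera adjusted p = 1.726e-22, and 0.00158 with an estimated correlation). Creld2 rose 8.91-fold (log2 change 3.16 ± 0.13 SE, adjusted p = 2.358e-08), Manf 5.04-fold, Sdf2l1 4.19-fold, Hspa5, the chaperone BiP, 3.72-fold and Hsp90b1 2.71-fold. Of 21 genes of glucose production and insulin signalling 12 fell, 13 adjusted over the list alone (median −0.56, camera adjusted p = 5.829e-09, and 0.0158 with an estimated correlation), with Ppp1r3g, a glycogen-targeting subunit, 32.4-fold lower and G6pc 2.23-fold lower. Of 17 lipid droplet proteins 8 fell, 10 adjusted over the list alone (camera adjusted p = 0.002367, and 0.0379 with an estimated correlation), among them Plin2 by 2.34-fold, Plin5 by 2.41-fold and the lipase gene Pnpla2 by 2.34-fold. Cidec fell 3.94-fold (adjusted p = 0.03114), a call lost in 6 of 19 alternatives, and Cidea was not tested because its counts were too low.

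Other liver input genes moved with diet too. Cyp26a1, which degrades retinoic acid, rose 10.8-fold and Cyp7b1, an oxysterol hydroxylase, 4.09-fold. Sqle, of cholesterol synthesis, rose 1.81-fold, while Cyp7a1 did not pass (log2 change −0.37 ± 0.16 SE, edgeR adjusted p = 0.1194) except without input low-fat 1 (−0.53, adjusted p = 2.105e-05). Mir122 (chromosome 18, 65248861 to 65248926) had 42.3 ± 10.7 TMM-scaled CPM on high fat and 1.94 ± 1.63 on low fat (SD, n = 3 each), a 24.7-fold difference that rests on 3 to 9 counts per low-fat library. Of 17 endothelial markers 3 fell (camera adjusted p = 0.009056; adjusted p = 0.11 with an estimated correlation), Stab1 by 3.33-fold and Stab2 by 2.37-fold. Of 19 immediate early genes 7 fell and 1 rose, 8 and 1 adjusted over the list alone (camera adjusted p = 0.03458; adjusted p = 0.3 with an estimated correlation). Of 10865 tested genes 964 rose and 1482 fell. Input low-fat 1 stood apart from the other input libraries, with 0.0847% of its counts in snoRNA genes against 0.0114% or less. Low-fat 2 and 3 differed from the rest in another way. Mitochondrial tRNA genes took 0.0572 and 0.0614% of their counts, against 0.1844 to 0.3941% in the other input libraries. Without input low-fat 1, 4728 genes were called, 2460 higher and 2268 lower, so the excess of falls was not kept there (RLE factors gave 1150 and 1327). Every fit without input low-fat 1 leaves only the close pair, low-fat 2 and 3, as low-fat input. Their spread may be technical, so such fits may call too many genes, and the call of Cyp7a1 rests on one. The count was 1575, 1427 and 1583 without input high-fat 1, 2 and 3, 1336 when only the groups compared entered the fit and 1056 with the close pairs of input libraries summed.

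**Figure D2:**
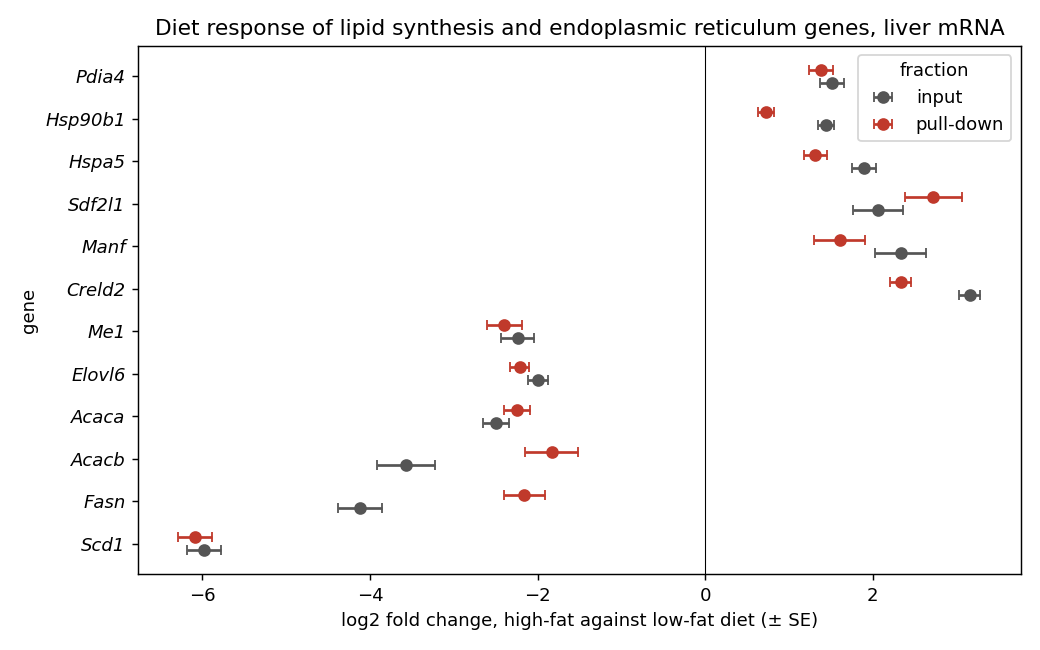
Log2 change on high against low fat of 12 named genes in liver mRNA input (grey) and pull-down (red), with bars of 1 standard error from the edgeR fit. Scd1 fell by 5.98 in input and fell by 6.08 in pull-down, and Creld2 rose by 3.16 and 2.33.

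The diet response was also read in the tagged RNA of liver. Scd1 fell 67.7-fold in pull-down, from 5247 ± 1104 to 77.4 ± 2.64 TMM-scaled CPM (SD, n = 3 each; log2 change −6.08 ± 0.20 SE, edgeR adjusted p = 3.846e-09). Of 25 fatty acid and triglyceride synthesis genes 10 fell, 20 adjusted over the list alone (median −0.77, camera adjusted p = 4.01e-39, and 2.47e-04 with an estimated correlation), Acaca by 4.74-fold, Elovl6 by 4.64-fold and the malic enzyme gene Me1 by 5.26-fold. Of 23 unfolded protein response genes 16 rose, 18 adjusted over the list alone (median 0.79, camera adjusted p = 1.848e-26, and 7.36e-04 with an estimated correlation), Sdf2l1 by 6.60-fold, Creld2 by 5.04-fold, Pdia4 by 2.60-fold and Hspa5 by 2.48-fold. Of 21 genes of glucose production and insulin signalling 7 fell and 1 rose, 11 and 2 adjusted over the list alone (camera adjusted p = 1.96e-09, and 0.00968 with an estimated correlation), with Ppp1r3g 24.5-fold, Ppargc1a 3.82-fold and Igfbp1 2.28-fold lower. Of 31 genes of fatty acid oxidation and PPAR-alpha targets 4 fell, 6 adjusted over the list alone (camera adjusted p = 0.004925, and 0.0329 with an estimated correlation): Acot3 fell 4.99-fold, Cyp4a10 4.87-fold and Cyp4a14 3.82-fold. Of 21 bile acid genes 6 fell and 1 rose, 7 and 2 adjusted over the list alone (camera adjusted p = 0.01615; adjusted p = 0.201 with an estimated correlation), Cyp7a1 by 1.82-fold. Selenbp2 rose 6.55-fold, Cyp26a1 4.21-fold and Sqle 2.11-fold. Cyp4a, Selenbp and Acot genes have close copies that could share reads.

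In liver pull-down 310 genes rose and 337 fell on high fat. The count was 1982 without input low-fat 1, 335, 390 and 354 without pull-down high-fat 1, 2 and 3, 422 and 369 without pull-down low-fat 1 and 2, and 1540 when only the groups compared entered the fit. Of the 377 genes called in both fractions 367 went the same way, 160 up where independent lists would share 27.5 and 207 down against 46.0. Across genes, which are not independent replicates, the diet changes of the fractions correlated at r = 0.429 and rho = 0.347. The difference between the fractions in the diet response passed the test for 293 genes. The fall on high fat was smaller in pull-down for Fasn (difference of log2 changes 1.96 ± 0.34 SE, edgeR adjusted p = 0.02097), for Srebf1, the transcription factor of lipid synthesis (1.68 ± 0.25), and for Acss2 (1.08 ± 0.18). The response of Mir122 was lower in pull-down (−3.81 ± 0.57, adjusted p = 0.01537), as were those of Cyp26a1 (−1.36 ± 0.25) and Elovl5 (−0.68 ± 0.14). Of the 12 fits without 1 library 11 moved the count by over 1.5 times. It was 3024 without input low-fat 1 (leaving only the close pair as low-fat input), 0 without pull-down low-fat 3, and 74 or less without any other library but pull-down low-fat 1. It was 0 with the close pairs of input libraries summed and 741 with DESeq2. With the replicate number as a block among the pull-down libraries it was 115, with Elovl5 at an adjusted p of 0.05123, and with input and pull-down of equal number paired it was 0. In that difference 4 fatty acid and triglyceride synthesis genes were higher and 1 lower of 25, 5 and 1 adjusted over the list alone (camera adjusted p = 0.01998; adjusted p = 0.477 with an estimated correlation).

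In kidney no gene passed for diet. In input edgeR called 0 of 15023 genes, with 2582 at an unadjusted p under 0.05 and 540 called by DESeq2. In pull-down edgeR called 0 (718 at an unadjusted p under 0.05, 0 by DESeq2), and for the difference between the fractions 0 (1970 at an unadjusted p under 0.05, 101 by DESeq2). The ribosomal protein list shifted up in input (median 0.68, 15 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.024e-06; adjusted p = 0.64 with an estimated correlation) and down in pull-down (median −0.54, 0 adjusted over the list alone; camera adjusted p = 1.597e-10; adjusted p = 0.387 with an estimated correlation). Across genes the diet changes of the fractions correlated at r = −0.036 (−0.0719 to 0.0118 with single libraries left out) and rho = −0.114, and at r = −0.253 in the upper part by expression. In simulated data of this design the test recovered 34% of genes set to a 2-fold diet change in kidney input. Kidney input high-fat 1 stood apart from the other high-fat input libraries. Input high-fat 1 and low-fat 1 held 16.6 and 17.6% of their counts in mitochondrial mRNA, against 11.6 to 12.0% in the other 3 input libraries. Without input high-fat 1, 2525 genes were called for diet in input and 1397 for the difference, and without input low-fat 1 these counts were 140 and 2.

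Small RNA libraries of liver and VsWAT lost small RNA classes in pull-down. The share of counts in microRNA genes fell from 2.66 ± 0.593% in liver input (SD, n = 6) to 0.724 ± 0.342% in pull-down (SD, n = 5; two-sided exact permutation p = 0.002165, adjusted p = 0.004996 over 30 shares). In VsWAT it fell from 1.62 ± 0.189% to 0.357 ± 0.14% (SD, n = 6 each; exact permutation p = 0.002165). The largest part was Mir6236, whose sequence lies in ribosomal RNA, and without it the shares went from 0.522 to 0.126% in liver (exact p = 0.004329) and from 0.291 to 0.0704% in VsWAT (exact p = 0.002165). The snoRNA share fell from 3.19 to 0.455% in liver (exact p = 0.004329) and from 3.11 to 0.384% in VsWAT (exact p = 0.002165), and the tRNA share from 2.54 to 0.303% (exact p = 0.004329) and from 4.3 to 0.624% (exact p = 0.002165). Protein-coding genes took 39.1 ± 4.56% of input and 57.8 ± 3.89% of pull-down counts in liver and 41.5 ± 2.67% and 58.7 ± 5.04% in VsWAT. Mitochondrial mRNA rose from 4.04 to 10.5% in liver and from 1.87 ± 0.223% to 14.7 ± 3.76% in VsWAT (both exact p = 0.002165, adjusted p = 0.007732 over 25 parts of classes). By gene, edgeR called 0 of the 7 mitochondrial mRNAs in liver small RNA (median 0.13 with TMM factors and 1.30 with total counts; camera adjusted p = 0.6475). In plasma the microRNA share did not differ by the test, at 1.69 ± 0.819% in input and 2.14 ± 0.414% in pull-down (SD, n = 4 each; exact permutation p = 0.3714), while the mitochondrial share rose from 1.09 ± 0.518% to 8.64 ± 1.17% (exact p = 0.02857, the smallest that 4 against 4 allow; adjusted p = 0.04081).

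**Figure D3:**
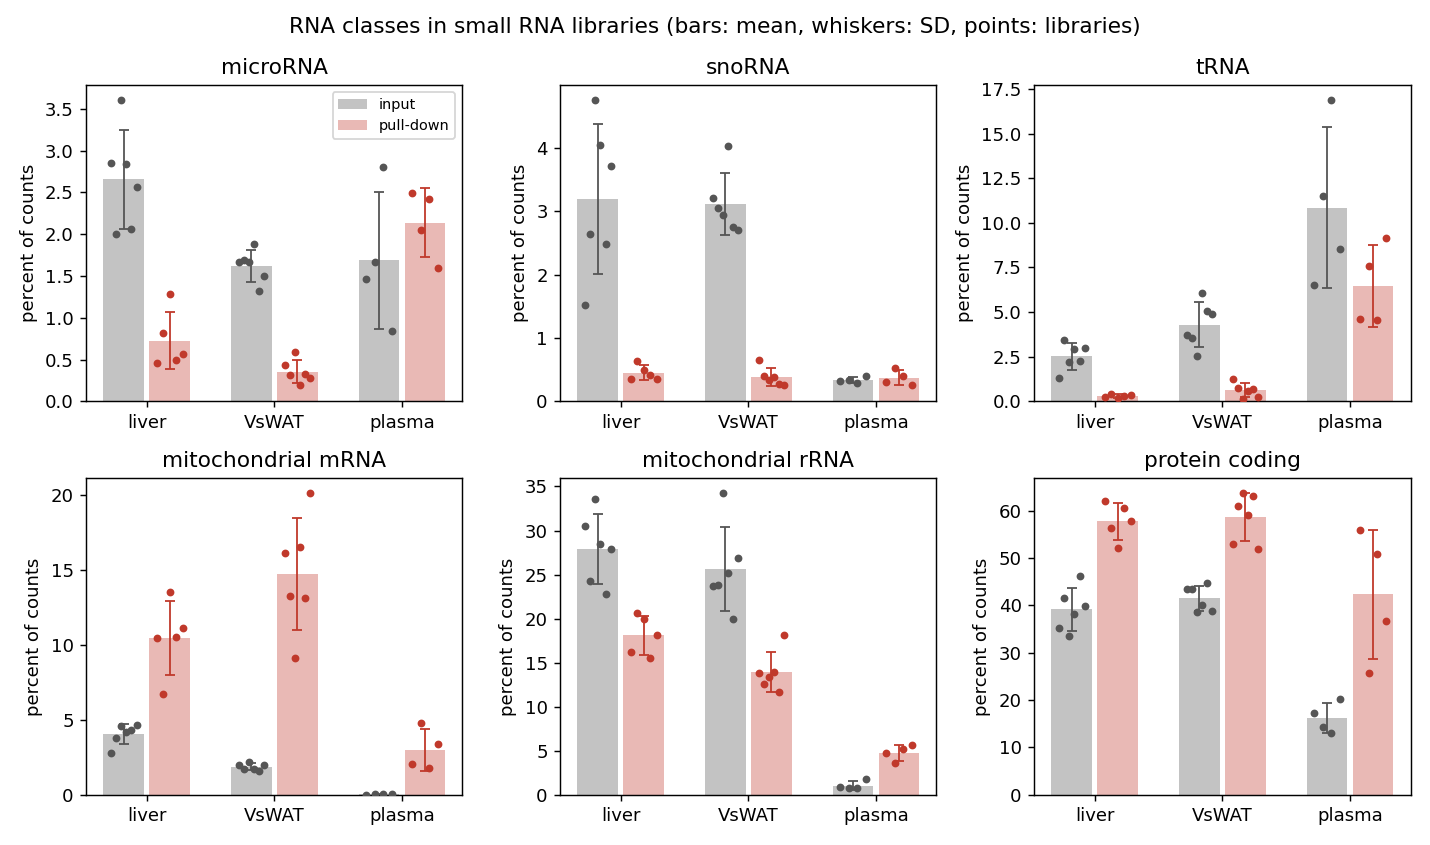
Share of counts, in percent, by RNA class in input and pull-down small RNA libraries of liver, VsWAT and plasma; bars are means, whiskers SD and points libraries. The microRNA share was lower in pull-down in liver (2.66 to 0.724%) and VsWAT (1.62 to 0.357%).

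Within liver small RNA the microRNA genes tested were almost all lower in pull-down. Of 40 microRNA genes 37 fell and 1 rose, and of 5 liver-enriched microRNAs all 5 fell (median −4.58, camera adjusted p = 3.004e-06; adjusted p = 0.214 with an estimated correlation). Mir122 fell 8.65-fold (log2 change −3.11 ± 0.39 SE, edgeR adjusted p = 1.016e-05) and Mir192 13.7-fold. Mir148a, with 7 counts in all pull-down libraries, fell 95-fold, Mir30a 42.8-fold and Mir328 100.3-fold. Mir33 was not tested because its counts were too low. All 12 abundant structured small RNAs fell (median −3.69, camera adjusted p = 7.453e-13; adjusted p = 0.203 with an estimated correlation), with the Y RNAs Rny1 and Rny3 15.2- and 21.9-fold lower. All 14 mitochondrial tRNA and rRNA genes fell (median −3.39, camera adjusted p = 4.153e-11; adjusted p = 0.214 with an estimated correlation). Among mRNA fragments, 15 of 16 endothelial markers fell (camera adjusted p = 4.322e-09), Stab1 by 5.78-fold, all 14 macrophage markers fell (camera adjusted p = 4.112e-08), Csf1r by 4.91-fold, all 10 stellate cell and fibroblast markers fell (camera adjusted p = 2.525e-05) and all 12 extracellular matrix genes fell (camera adjusted p = 2.791e-06), with adjusted p of 0.203 or 0.214 with an estimated correlation for these 4 lists. The list-alone counts were the same. Wdr75, Cyp7a1 and Baz1a rose 3.70-, 3.59- and 3.45-fold. Of 8401 genes 2271 rose and 2379 fell.

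Scaling decided the direction of several groups here. Total-count scaling moved the median of all liver small RNA genes from 0.10 to 1.23 and gave 5726 genes higher and 708 lower. Alb fell 2.15-fold (log2 change −1.10 ± 0.26 SE, edgeR adjusted p = 0.002321) and read 0.02 with total counts. The median of 23 hepatocyte markers, of which 19 fell (camera adjusted p = 0.003301; adjusted p = 0.683 with an estimated correlation), went from −1.02 to 0.12, that of 26 respiratory chain genes, of which 21 fell (camera adjusted p = 7.21e-05; adjusted p = 0.683 with an estimated correlation), from −0.90 to 0.25, and that of 34 ribosomal protein genes, of which 17 fell and 1 rose (camera adjusted p = 0.003301; adjusted p = 0.949 with an estimated correlation), from −0.57 to 0.58. The microRNA, structured RNA and non-hepatocyte lists kept their sign.

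In VsWAT small RNA, transcripts of fat cells were higher in pull-down and those of stromal and vascular cells lower. Of 18 adipocyte markers 11 rose and 3 fell (median 0.70, camera adjusted p = 0.002146; adjusted p = 0.13 with an estimated correlation), with Pparg, the regulator of fat cell differentiation, 4.56-fold higher (log2 change 2.19 ± 0.23 SE, edgeR adjusted p = 3.098e-06), Cebpa 3.63-fold, Plin1 2.26-fold and the lipase gene Lipe 2.01-fold higher. Rgcc rose 6.98-fold. All 7 tested mitochondrial mRNAs rose (median 2.41, camera adjusted p = 1.973e-09; adjusted p = 0.117 with an estimated correlation), mt-Cytb by 6.03-fold and mt-Nd2 by 5.68-fold. All 15 stellate cell and fibroblast markers fell (median −1.75, camera adjusted p = 1.277e-11, and 0.013 with an estimated correlation), Pdgfra by 3.48-fold, and 20 of 24 extracellular matrix genes fell, 21 adjusted over the list alone (median −1.68, camera adjusted p = 5.498e-14, and 0.0418 with an estimated correlation), Timp2 being 5.44-fold lower. All 16 endothelial markers fell (camera adjusted p = 4.269e-07; adjusted p = 0.117 with an estimated correlation), Stab1, shared with macrophages, by 5.40-fold. Of 18 macrophage markers 14 fell (camera adjusted p = 3.231e-07; adjusted p = 0.117 with an estimated correlation), Csf1r by 3.80-fold. All 8 tested mesothelial and epididymal genes fell (camera adjusted p = 7.617e-04; adjusted p = 0.287 with an estimated correlation), Msln by 5.10-fold. Of 63 microRNA genes 48 fell and none rose, Mir328 by 91.9-fold and Mirlet7c-1 by 32.3-fold. Of 14 structured small RNAs 12 fell (camera adjusted p = 8.247e-18, and 0.0418 with an estimated correlation), Rmrp by 23.4-fold and Rn7sk by 9.14-fold.

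In VsWAT pull-down 2372 of 11339 genes were higher and 2609 lower, and with total-count scaling 5322 and 1157, with the median of all genes moved from 0.01 to 0.64. Of 7613 genes tested in the small RNA of both liver and VsWAT 1096 rose in both, where independent lists would share 517.7 (Fisher's exact test p = 4.078e-240), and 1267 fell in both against 452.6. The Xist transcript, made by the inactive X chromosome, had 270 to 4615 counts in each liver small RNA library and 479 to 1920 in each VsWAT small RNA library, with 0 to 4 counts of Y-linked genes. Liver mRNA libraries had 2 to 33 Xist counts and 618 to 2716 Y-linked counts, so comparisons of liver small RNA with liver mRNA also compare libraries that differ in these transcripts.

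**Figure D4:**
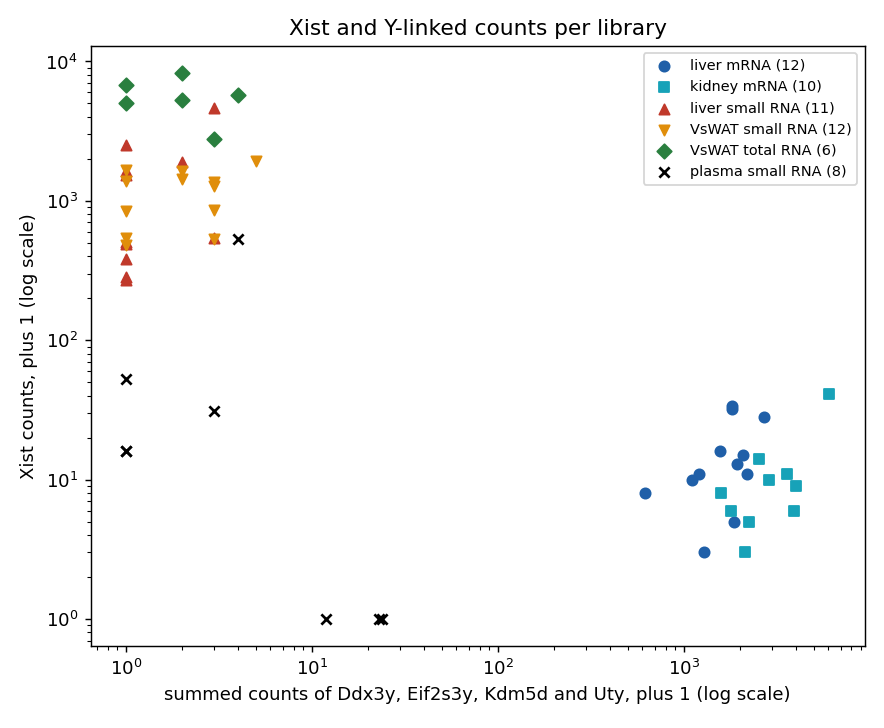
Xist counts plus 1 (vertical, log axis) against summed counts of Y-linked genes plus 1 (horizontal, log axis), 1 point per library. Liver and kidney mRNA libraries had at most 40 Xist counts and at least 618 Y-linked counts, and liver small RNA, VsWAT small RNA and VsWAT total RNA libraries at least 270 and at most 4.

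In plasma, mitochondrial mRNAs were higher in pull-down, in few and shallow libraries. Of 7 mitochondrial mRNAs 6 rose, 7 adjusted over the list alone (median 5.34, camera adjusted p = 1.054e-16; adjusted p = 0.257 with an estimated correlation), with mt-Nd2 102.4-fold higher (log2 change 6.68 ± 1.02 SE, edgeR adjusted p = 0.01054), mt-Nd1 96.5-fold and mt-Nd4 92.3-fold higher. The globin gene Hba-a1, which has a near-identical copy, fell 18.3-fold (adjusted p = 0.01081), and of 9 erythroid and platelet genes 1 fell, 7 adjusted over the list alone (camera adjusted p = 1.588e-04; adjusted p = 0.348 with an estimated correlation). Mir484 had 567 counts in input and 0 in pull-down, at least 122-fold lower with a floor of 3 counts over the pull-down libraries. Alb did not pass (log2 change 4.05 ± 1.39 SE, adjusted p = 0.189) but did in 5 of 15 alternatives, with DESeq2 at an adjusted p of 0.0176. Of 13 hepatocyte markers 0 passed and 4 were higher adjusted over the list alone (median 4.05, camera adjusted p = 9.551e-06; adjusted p = 0.348 with an estimated correlation), and of 8 acute phase genes 0 passed and 5 were higher adjusted over the list alone (median 4.25, camera adjusted p = 4.95e-05; adjusted p = 0.309 with an estimated correlation). The summed hepatocyte markers held 19020 and 347.2 CPM in pull-down high-fat 1 and 2 and 1171 and 5855 in low-fat 1 and 2. The highest input library held 256.8 CPM, so the size of this shift rests on single libraries. Mir122 did not pass (log2 change −1.43 ± 1.00 SE, adjusted p = 0.4746) and was positive with total-count scaling (0.79).

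Plasma counts of called genes moved with single libraries. Of 3469 genes tested 6 were higher and 11 lower, with RLE factors 6 and 5, with total counts 31 and 4, and with DESeq2 213 in all; in simulated plasma data 16 of the 35 genes that DESeq2 called (45.7%) had not been changed. Each of the 8 fits without 1 library moved the count by over 1.5 times, from 0 without pull-down low-fat 2 to 443 without pull-down high-fat 2, and total counts moved the median of all genes from 0.04 to 2.11. The plasma libraries also differed in sex-linked transcripts. Input low-fat 2, pull-down high-fat 2 and pull-down low-fat 2 had 0 Xist counts and 23, 22 and 11 Y-linked counts, while the other 5 had 15 to 531 Xist counts and 0 to 3 Y-linked counts, so plasma comparisons also compare libraries that differ in these. Of the 11 genes lower in plasma all 11 were lower in liver small RNA pull-down, where 3.69 would be shared by independent lists (Fisher's exact test p = 5.877e-06). Among these 11 genes, 6 are tRNA genes and 1 a microRNA gene. In liver small RNA 125 of 128 tRNA genes and 37 of 40 microRNA genes were lower, so this test largely restates the behaviour of classes. Of the 6 higher in plasma all 6 were higher in VsWAT (expected 1.47, Fisher's exact test p = 2.158e-04) and 0 in liver (expected 1.71, Fisher's exact test p = 0.1925). These 6 are all mitochondrial mRNAs, 1 class of transcripts, so the last 2 tests restate the behaviour of that class and do not count 6 independent genes. For diet edgeR called 0 genes in plasma input (0 at an unadjusted p under 0.05, 0 by DESeq2), 0 in pull-down (453 at an unadjusted p under 0.05, 125 by DESeq2) and 0 for the difference between the fractions (209 at an unadjusted p under 0.05, 0 by DESeq2). Without input low-fat 1 the input count was 1 and without pull-down high-fat 1 the pull-down count was 2. In simulated data of this design the test recovered 0% of genes set to a 2-fold pull-down change in plasma.

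The diet response of lipid synthesis was also present in liver small RNA. Scd1 fell 32.1-fold on high fat in input (log2 change −5.01 ± 0.48 SE, edgeR adjusted p = 1.181e-04) and 18.8-fold in pull-down (−4.23 ± 0.48, adjusted p = 0.001198). Of 23 fatty acid and triglyceride synthesis genes 4 fell in input, 14 adjusted over the list alone (median −1.03, camera adjusted p = 9.179e-34; adjusted p = 0.0557 with an estimated correlation), Acss2 by 6.77-fold, Elovl6 by 6.34-fold and Me1 by 3.85-fold. Of 16 immediate early genes 1 rose in input, with 11 higher and 1 lower adjusted over the list alone (median 1.07, camera adjusted p = 1.977e-11, and 0.00695 with an estimated correlation), and 0 in pull-down, 7 adjusted over the list alone (median 1.21, camera adjusted p = 5.867e-13, and 0.00226 with an estimated correlation). The member that passed in input was Egr1, 7.10-fold higher (adjusted p = 0.01108). Chka rose 5.82-fold and the hepcidin gene Hamp2, which has a close copy, fell 10.4-fold in input and 7.64-fold in pull-down, where Nfil3, a repressor within the clock, rose 5.83-fold. edgeR called 7 genes higher and 10 lower in input and 1 higher and 2 lower in pull-down. For the difference between the fractions it called 0, with 331 at an unadjusted p under 0.05 and 0 by DESeq2. Of the 11 fits without 1 library 8 moved the input count by over 1.5 times, to between 2 (input low-fat 2) and 34 (pull-down high-fat 3), and the pull-down count ranged from 1 (input high-fat 2 or pull-down low-fat 3) to 7 (input high-fat 3). With only the groups compared in the fit the counts were 7 and 6.

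In VsWAT, transcripts of lipid synthesis were lower on high fat in each of the 3 kinds of library. In total RNA, Acly, which makes cytosolic acetyl-CoA, fell 14.7-fold (log2 change −3.88 ± 0.34 SE, edgeR adjusted p = 0.003348), Elovl6 20.4-fold, Fasn 12.7-fold, Acaca 10.5-fold, Thrsp 8.78-fold, Acss2 7.62-fold, the pentose phosphate enzyme gene Tkt 12.7-fold and Pygl 4.32-fold. Of 22 fatty acid and triglyceride synthesis genes 8 fell, 18 adjusted over the list alone (median −1.68, camera adjusted p = 2.781e-49; adjusted p = 0.241 with an estimated correlation). Lrg1, a secreted glycoprotein gene, rose 4.15-fold (log2 change 2.06 ± 0.15 SE, adjusted p = 0.002028), the imprinted gene Peg3 4.27-fold and Sfrp5 3.24-fold, while the clock repressor gene Nr1d1 fell 2.28-fold. Of 17 clock genes 1 fell, 4 adjusted over the list alone (camera adjusted p = 8.686e-04; adjusted p = 0.241 with an estimated correlation). The hormone genes Lep (0.47 ± 0.25, adjusted p = 0.4734) and Adipoq (0.09 ± 0.16, adjusted p = 0.8545) did not pass, nor did Scd1 (−0.89 ± 0.38, adjusted p = 0.3765) except with no low-count filter (adjusted p = 0.003063). edgeR called 10 genes higher and 24 lower of 12248, and DESeq2 176 in all. The count was 5, 4 and 11 without high-fat 1, 2 and 3, and 73 and 61 without low-fat 1 and 2.

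A part of these genes also fell in VsWAT small RNA. In input Acly fell 12-fold (log2 change −3.59 ± 0.40 SE, edgeR adjusted p = 0.001451), Tkt 11.3-fold, Fasn 8.98-fold, Acaca 8.36-fold and Thrsp 8.11-fold, and Lrg1 rose 4.50-fold. Of 22 fatty acid and triglyceride synthesis genes 6 fell, 18 adjusted over the list alone (median −1.30, camera adjusted p = 4.822e-63, and 0.00859 with an estimated correlation). In pull-down Elovl6 fell 13.5-fold, Acly 10.4-fold, Acaca 8.20-fold, Fasn 6.95-fold and Thrsp 4.69-fold, while Lrg1 rose 4.06-fold, Peg3 4.12-fold, the heme oxygenase gene Hmox1 4.76-fold and the collagen gene Col6a3 2.06-fold. There 8 of the 22 fatty acid and triglyceride synthesis genes fell, 13 adjusted over the list alone (median −1.03, camera adjusted p = 2.783e-25, and 0.049 with an estimated correlation). edgeR called 1 gene higher and 8 lower in input and 16 higher and 30 lower in pull-down, a balance that turned with DESeq2 (83 and 48) and without a filter (252 and 123), and the 9 genes called in both fractions went the same way. The difference between the fractions gave 0 genes (475 at an unadjusted p under 0.05, 2 by DESeq2). The input count was 3, 2 and 2 without input high-fat 1, 2 and 3 and 15 without input low-fat 1. Input high-fat 1 and 2 were close to each other (chi-square per degree of freedom 1.527), so the spread within high fat may be partly technical. The pull-down count was 8 when only the groups compared entered the fit, and 8 of the 12 fits without 1 library moved it by over 1.5 times, to between 1 (pull-down high-fat 2) and 29 (pull-down low-fat 1). In simulated data of this design the test recovered 22% of genes set to a 2-fold diet change in input and 28% in pull-down.

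**Figure D5:**
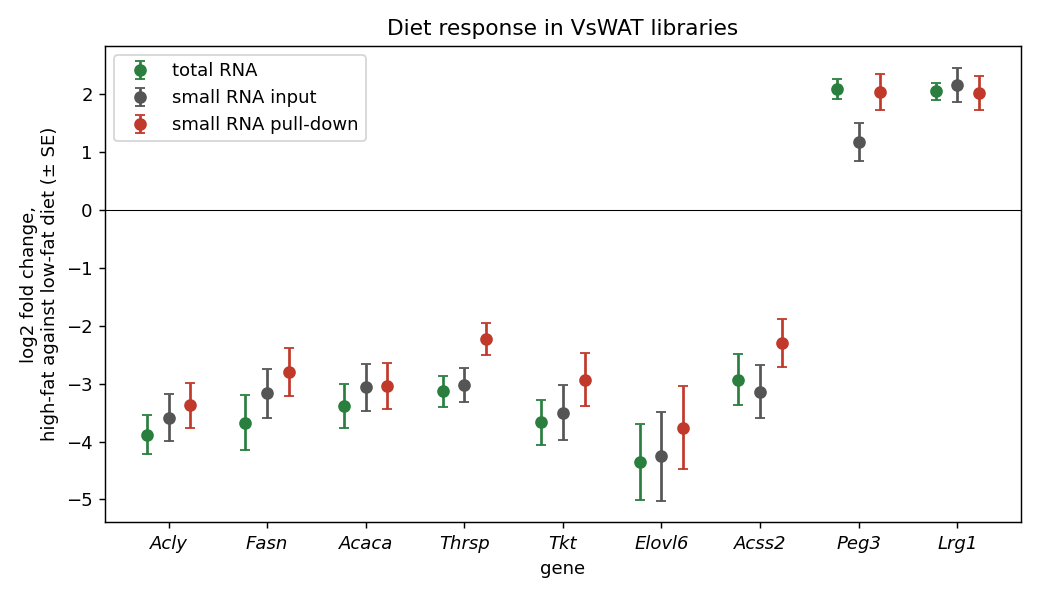
Log2 change on high against low fat of 9 named genes in VsWAT total RNA, small RNA input and small RNA pull-down, with bars of 1 standard error from the edgeR fits. Acly lay at −3.88, −3.59 and −3.38 in the 3 kinds of library, and Lrg1 rose by 2.06, 2.17 and 2.02.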

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

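The tests of explanations and the other splits of the libraries were chosen after the results were seen, except the test of gene span and expression level. For sex-biased liver genes the prediction is recorded as written before its test, but the genes were singled out after values were seen. The contrasts and the fits without single libraries were set before. A result is listed because a test of the difference itself found that a change differed between liver and kidney, or that the diet response differed between pull-down and input. No group holds more than 3 libraries, so single libraries far from their group were not tested for.

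The pull-down change differed between liver and kidney for 1742 genes. Among the named genes the difference, liver minus kidney in log2, was 4.368 for Nr0b2, 3.556 for Cyp7a1, 3.247 for Egf, −1.759 for Aqp1, −1.893 for Reln, −1.958 for Slc13a3, −3.113 for Lrat and −3.172 for Acaa1b. In 100 splits drawn from those that keep the group sizes, 1 (the real one) called as many genes, and the highest other count was 1618, close to the real count. The splits redraw the fraction within each tissue and diet. This breaks the pull-down change shared by the tissues as well, so they cannot test the difference alone.

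The diet response differed between pull-down and input of liver mRNA for 293 genes. Among the named genes the difference, pull-down minus input in log2, was 1.962 for Fasn, 1.679 for Srebf1, 1.085 for Acss2, −0.6778 for Elovl5, −1.359 for Cyp26a1 and −3.805 for Mir122. Of 100 splits 4 called as many genes, which is under 0.05, but these splits do not keep replicate numbers together, and the highest other split called 685 genes, which points to a structure of the samples besides the groups. Such splits redraw the diet within each fraction. This breaks the diet response shared by the fractions as well, so they cannot test the difference alone. The count was 115 with the number as a block among pull-down libraries and moved between 0 and 3024 when single libraries were left out, so a chance split is not taken as excluded.

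Ribosomal protein and respiratory chain genes were lower and clock genes higher in pull-down of both liver and kidney. Gene span and expression level are argued against as the whole cause, since 6 of 6 list medians lay outside the central 95% of 10000 random lists matched on both, the closest being ribosomal proteins in kidney (−1.22 against −1.2 to −0.25). The matched lists fell too, with medians in liver and kidney of −1.03 and −0.774 for ribosomal proteins and −0.701 and −0.628 for the respiratory chain. For clock genes they were −0.119 and −0.158. A part of the falls may therefore go with span and expression. The span is genomic, so transcript length was not tested. Scaling is argued against too, since total counts moved the median of all genes by at most 0.248, less than any of the 6 list medians. A loss of RNA only from cells other than hepatocytes is argued against as the whole cause in liver, because hepatocyte markers fell as well (median −1.65, with −0.998 to 0.334 in random lists matched on expression alone). Endothelial, stellate cell and macrophage medians fell further (−2.122, −2.199 and −1.763), so a loss from those cells beside another cause stays open. A candidate explanation that stays open is that the tag marks recently made RNA, so that long-lived transcripts are recovered less; no RNA half-lives were used here and it was not tested.

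Liver small RNA libraries held Xist and almost no Y-linked counts, while the series design text describes male mice. A failure of these libraries to capture Y-linked transcripts is argued against, because the 4 Y-linked genes had 5 counts in all, where sets of 4 genes matched on their liver mRNA level had at least 1840 in the central 95% of draws. Female animals remain a candidate explanation: in 11 of 11 liver small RNA libraries the score of female-biased minus male-biased liver genes exceeded that of every liver mRNA library (4.094 to 5.497 against −7.034 to −5.725). For example, Sult3a1 averaged 647.1 CPM in liver small RNA and 0.0337 in liver mRNA, and Cyp2d9 0.524 and 785.8. VsWAT libraries also held Xist (479 or more counts) and at most 4 Y-linked counts, and a mix-up of labels between animals was not tested apart from this.

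Hepatocyte transcripts in VsWAT followed the library number across separate libraries. Small RNA input high-fat 1 and 2 were close to each other, so the 6 numbers may not be 6 separate samples. Over the 6 numbers, log2 Alb in small RNA input and total RNA correlated at r = 0.917 (exact permutation p = 0.0139, adjusted p = 0.0153 over 3 pairs; rho = 0.829, p = 0.0583; r = 0.693 without the 2 farthest samples), which argues against reads mixed between libraries of one preparation. Input and pull-down correlated at r = 0.953 (exact permutation p = 0.0153, adjusted p = 0.0153; rho = 0.829, p = 0.0583; r = 0.894 without the 2 farthest), and pull-down and total RNA at r = 0.957 (exact permutation p = 0.00139, adjusted p = 0.00417; rho = 1, p = 0.00278; r = 0.936). A single source of liver RNA in the tissue samples may explain this, since 21 other hepatocyte markers, none of them shared with the adipocyte list, went with Alb across the 6 input libraries (median r = 0.945, against −0.254 to 0.291 in matched random lists; 19 of 21 over 0.5), as did most in pull-down (0.978; 19 of 21) and total RNA (0.932; 12 of 16), though low-fat 2 held much of the summed markers with little Alb in pull-down (3579 and 94.02 CPM) and total RNA (1188 and 24.84). Plasma RNA as sequenced in input is argued against as that source for VsWAT small RNA input. The lowest VsWAT input library held 107.7 CPM of Alb and 618.1 of summed markers and the highest plasma input library 55.02 and 256.8. In pull-down the order turned, with 6280 and 19020 CPM in plasma high-fat 1 and at most 1097 and 3579 in VsWAT, so those libraries do not argue against it. Dissection and transfer within the animal stay open and were not tested.

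Pull-down against input was compared with other splits of the libraries as well. In liver mRNA 1 of 100 splits, the real one, called as many genes (8022, highest other 3832), in VsWAT small RNA 1 of 100 (4981, highest other 622), in liver small RNA 1 of 100 (4650, highest other 2740) and in kidney 1 of 60 (7961, highest other 3105). This argues against a chance split for these 4 but does not exclude it, since no share under 1 in 100 (1 in 60 in kidney) could be reached. The splits also treat libraries as separate samples, which the labels do not say. For the difference of diet responses in VsWAT small RNA the real count was 0, so 100 of 100 splits reached it, with a highest other count of 132. In plasma 2 of 18 splits called as many genes (17, highest other 23), and 18 splits are too few for a share under 0.05. For diet 10 splits are too few for that share in any set: liver mRNA input had 2446 genes (1 split; highest other 0), liver mRNA pull-down 647 (1; 0), liver small RNA input 17 (1; 0), VsWAT small RNA input 9 (1; 0), VsWAT total RNA 34 (1; 9) and VsWAT small RNA pull-down 46 (2; 104). The split with 104 genes set high-fat 1, high-fat 2 and low-fat 1 apart, the 3 pull-down libraries with the most Alb, which points to a structure of the samples.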

How the results depend on the processing

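Total-count scaling, summed close pairs of liver input libraries, the combined omissions and the crossed pairing were chosen after the results were seen. Pull-down counts in liver mRNA (7785 to 8596 with single libraries left out), kidney (6068 to 8552), liver small RNA (3926 to 4628) and VsWAT (4377 to 5261) stayed within 1.5 times under all settings run, but counts of calls do not say which genes were called. Diet counts and plasma counts did not, and the causes were not tested. Of the values of named genes under other settings 3067 kept direction and side of the threshold, 189 lost the call, 8 gained one and 4 turned: Lrp2 in kidney (0.06055 without input high-fat 1 and 0.1456 with total counts; −0.1744 to 0.06055 with single libraries left out), Alb in liver small RNA (0.01817 with total counts) and Mir122 in plasma (0.7867 with total counts). Of class shares 311 were kept, 28 lost and 4 gained a call, and 5 turned: snoRNA in liver mRNA (−0.01153 to 0.004393 with single libraries left out, the latter without input low-fat 1), and in plasma with the most counted gene left out microRNA (−0.8951), snoRNA (−0.2262) and snRNA (−0.207), with snoRNA also between −0.0186 (without pull-down high-fat 2) and 0.07106 with single libraries left out.

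In liver mRNA the diet count in input was 1336 with only the groups compared and 1056 with close pairs summed (1427 to 4728 with single libraries left out). In pull-down it was 1540 with only the groups compared and 1549 with pairs summed and input low-fat 1 left out (335 to 1982). The difference between fractions was 741 with DESeq2, 482 without a filter, 445 at 10 CPM, 0 with pairs summed and 1882 with pairs summed and input low-fat 1 left out (0 to 3024). Kidney diet counts were 540 (DESeq2) and 1201 (no filter) in input (0 to 2525), 1 in pull-down without a filter, and 101 (DESeq2) and 635 (no filter) for the difference (0 to 1397); with input high-fat 2 and 3 both left out all were 0. The liver minus kidney count ranged from 1149 to 2642.

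In liver small RNA the diet count in input was 71 with DESeq2, 149 without a filter and 7 with only the groups compared (2 to 34), in pull-down 22, 80 and 6, with 7 under RLE (1 to 7), and for the difference 5 without a filter. In VsWAT small RNA it was 32, 131 and 19 in input (2 to 15), 131, 375 and 8 in pull-down (1 to 50), and for the difference 2 with DESeq2 and 89 without a filter. In VsWAT total RNA it was 176 with DESeq2 and 718 without a filter (4 to 73). The plasma pull-down count was 213 with DESeq2, 11 with RLE, 56 without a filter, 41 at 10 CPM and 35 with total counts (0 to 443). With pull-down high-fat 2 and low-fat 2 left out, where a lone library per diet is assumed to vary like the other groups, it was 2721 (these 2 are the pull-down libraries with Y-linked counts and no Xist), with 1 for diet in input, 4029 in pull-down and 2093 for the difference. Plasma diet counts in pull-down were 125 with DESeq2 and 1 without a filter (0 to 2), and 0 to 1 in input.

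Same-numbered input and pull-down libraries correlated over 0.1 in 5 of 6 pairs in VsWAT small RNA, 4 of 5 in liver small RNA, 1 of 6 in liver mRNA, 0 of 5 in kidney and 0 of 4 in plasma, so numbers were not taken to pair fractions. In VsWAT small RNA all 6 were positive (0.01995 to 0.4024, median 0.2618, against −0.1589 for other numbers), a hint of pairing in the data. With the replicate number as a block anyway, the difference between fractions in liver mRNA gave 0 genes, liver small RNA diet 42 in input and 22 in pull-down, VsWAT small RNA diet 14 and 73, the latter 38 higher and 35 lower (a block that ties equal numbers across diets, where 2 of 6 pairs correlated over 0.1), and plasma pull-down 42; other counts moved by less than 1.5 times. With the block among liver mRNA pull-down libraries only, chosen after the results were seen, the diet count in pull-down was 522 and the difference between fractions 115. Plasma input deviations across diets were opposed for equal numbers, and the crossed pairing as a block called 0 genes.

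Of 622 list tests 198 passed with the preset correlation, 23 with an estimated one and 138 with fry. Among genes of the upper part by expression the diet responses of input and pull-down correlated at 0.533 in liver mRNA, −0.253 in kidney, 0.426 in liver small RNA, 0.373 in VsWAT and 0.073 in plasma, against 0.429, −0.0359, 0.311, 0.264 and 0.0611 over all genes. With single libraries left out these ranged from 0.331 to 0.443, −0.0719 to 0.0118, 0.226 to 0.343, 0.204 to 0.325 and 0.0196 to 0.0358, so r over all genes changed sign in kidney, and in plasma it lay below its value from all libraries each time. Recovery in simulated data was lowest in plasma, where 8-fold pull-down changes were recovered for 2% of genes; low depth, a wide spread and groups of 2 were not separated.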

Other observations

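The diet contrasts of VsWAT were read further, in lists fixed at the start. In small RNA pull-down, extracellular matrix genes shifted up on high fat (1 of 24 higher, 9 adjusted over the list alone; median 0.58, camera adjusted p = 4.906e-11, and 0.04896 with an estimated correlation), as did stellate cell and fibroblast markers (0 of 15, 3 adjusted over the list alone; median 0.44, camera adjusted p = 8.173e-05, and 0.04896) and unfolded protein response genes (0 of 22; median 0.34, camera adjusted p = 4.731e-04, and 0.04896). Clock genes shifted down (0 of 18, 3 lower adjusted over the list alone; median −0.40, camera adjusted p = 0.003365, and 0.04896). Immediate early genes shifted up in pull-down (0 of 22, 12 adjusted over the list alone; median 1.17, camera adjusted p = 9.002e-09; adjusted p = 0.178 with an estimated correlation), in input (median 0.61, camera adjusted p = 2.407e-07; adjusted p = 0.288 with an estimated correlation) and in total RNA (0 of 20, 6 adjusted over the list alone; median 0.63, camera adjusted p = 4.071e-07; adjusted p = 0.608 with an estimated correlation). Hepatocyte markers, which set libraries apart there, had a median of 1.34 for diet in pull-down (0 of 22; camera adjusted p = 0.03633; adjusted p = 0.702 with an estimated correlation).

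Kidney pull-down was lower for further lists. Of 23 extracellular matrix genes 16 fell (1 higher and 16 lower adjusted over the list alone; median −1.06, camera adjusted p = 5.15e-04; adjusted p = 0.318 with an estimated correlation), of 12 cholangiocyte markers 6 (camera adjusted p = 0.006248; adjusted p = 0.283 with an estimated correlation), of 8 mesothelial and epididymal genes 6 (camera adjusted p = 0.006248; adjusted p = 0.283 with an estimated correlation), and of 18 interferon response genes 9 fell and 1 rose (camera adjusted p = 0.01661; adjusted p = 0.325 with an estimated correlation).

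Among the 13 mitochondrial mRNAs, mt-Co2 and mt-Nd4l had 0 counts in all 59 libraries, and mt-Atp8 had 1, mt-Atp6 16, mt-Nd3 29 and mt-Co3 34 counts in total. The other 7 ranged from 1504218 (mt-Nd6) to 5722063 (mt-Cytb), so statements on mitochondrial mRNA rest on those 7 genes.

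Alb had 6280 and 18.11 CPM in the high-fat plasma pull-down libraries 1 and 2 and 345.6 and 1767 in the low-fat ones, against 1.8 to 55.02 CPM in plasma input libraries. In VsWAT small RNA input it had 641.8, 893.9 and 107.7 CPM in high-fat 1, 2 and 3 and 1063, 142.6 and 261.6 in low-fat 1, 2 and 3.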
